A study of Homo sapiens with 16 samples.

How the data were processed

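G-quadruplexes (G4s), the 4-stranded structures that guanine-rich DNA can fold into, were mapped in A549 cells, an established human lung carcinoma line, by CUT&Tag. In this assay an antibody held on chromatin directs a transposase that cuts and tags the DNA around it. The antibody was BG4, which binds folded G4 DNA, and it was used after transfection of a control siRNA (siControl) or of siRNA against BAZ2A or BAZ2B, at 71 nM for 48 hours, per the labels' protocols. H3K4me3, the histone mark of active promoters, was mapped in the siControl cells. The 16 libraries fall into 4 groups of 4 replicates. Drosophila chromatin was added to the samples as a spike-in, per the labels' protocols. Whether it was used for scaling is not given in the sources used here.

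The processing notes of the submitters name Bowtie2 2.4.5, Picard, SAMtools 1.15.1, bedtools and MACS2 2.1.4, and the builds hg19 and dm6. Per the labels, the authors kept peaks found in at least 2 replicates, with the coordinates of the replicate that had the most peaks. The 4 deposited peak lists therefore hold 1 list per group, each with its peaks' positions, and no value per replicate. Peak names carry the name of 1 run per list. Some of these runs are numbered beyond 4, so the run could not be tied to a labelled replicate, and how the runs relate to the 4 labelled replicates is not given in the sources used here. Column 7 of the deposited lists is the fold enrichment (a ratio) that the authors' peak caller gave each peak, and column 9 of the deposited lists is the −log10 of its q-value. The fold is the authors' own value for a peak and was used here only to rank and describe peaks within a list. Read depth is not given in the sources used here. All coordinates are hg19, written 1-based.

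Peaks of different lists were counted as shared when they had at least 1 base in common. A knockdown peak with no siControl peak was called gained, and a siControl peak with no knockdown peak was called lost. Across the 3 BG4 lists, overlapping peaks were merged into loci, and each locus was classed by the lists that hold it. Shares carry 95% Wilson intervals, which cover counting error over peaks and not the spread between cultures. Fisher's exact tests were two-sided and compared sets of peaks with each other, since the conditions themselves could not be tested without values per replicate. Benjamini-Hochberg adjustment was applied over the 4 tests of H3K4me3 overlap, over the 72 tests of chromosome shares on H3K4me3 peaks and over the 48 tests of gained shares per chromosome. The tests of chromosome ends were not adjusted. Odds ratios stratified by quintile of fold are Mantel-Haenszel estimates.

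Both knockdown lists are compared with 1 siControl list, so a locus missing from that list by chance counts as gained in both. The number of such loci was set against a quasi-symmetry log-linear model, in which the 3 lists differ in length but every pair of lists is associated to the same degree. The model was simulated in 500 draws and refitted to each, and the p-value counts draws whose ratio of observed to fitted loci lay as far from 1. The draws treat loci as independent, so this p-value covers counting error over loci and not the spread between cultures. It was also tested on simulated lists. By its deviance, the model was rejected in 3 of 50 simulated sets with no added loci, and with 150 loci added to both knockdowns the model returned a mean excess of only 32.2 loci (SD 14.2) and was rejected in 23 of 50, so it understates a real shared gain. In a simulated pair of lists, 1700 of 1700 gained and 800 of 800 lost peaks were recovered. Shared peaks were shifted there by less than their width, so this recovery was all but fixed in advance. It checks the counting of overlaps only.

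The choices made before the data were examined were the tests, the alternatives and the rule for named loci, except where a later choice is stated. Not among these planned choices were the tests of chromosome shares on H3K4me3 peaks and the quintiles of H3K4me3 peaks. The summit distances and the direct comparison of the 2 knockdown lists were not planned either. The rule took, for each knockdown, the 10 gained, 10 lost and 5 shared peaks of highest fold, and the 5 H3K4me3 peaks of highest fold. Alternatives were a −log10 q of at least 5, lists of equal length, a reciprocal overlap of 50% and the stronger 50% of peaks. The lists were also used without chromosome M, chromosome Y and unplaced contigs. A distance of up to 1 kb was allowed in merging loci, and overlap with H3K4me3 was defined more strictly. An hg19 gene annotation and genome sequence were not used here, and no coordinates were converted between builds. Promoter overlap, G4 sequence motifs, gene lists and gene names, all planned, were therefore not analysed here, and loci are named by position. Computation used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.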

Results

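BG4 CUT&Tag in A549 lung carcinoma cells gave 3 lists of G4 peaks, after control siRNA, siRNA against BAZ2A and siRNA against BAZ2B, and H3K4me3 CUT&Tag gave a list of active promoter regions in the siControl cells. BAZ2A is the large subunit of the nucleolar remodelling complex that silences ribosomal RNA genes, and BAZ2B is a related bromodomain protein of chromatin remodelling complexes. The comparisons ask whether depletion of either protein changes where G4 structures are detected. Each list merges 4 replicates, so the values below have no replicate error, and no difference between conditions could be tested. The level of BAZ2A and BAZ2B after knockdown was not analysed here.

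Both knockdown lists were longer than the siControl list. The siControl list held 3332 BG4 peaks with a median width of 597 bp and covered 2.09 Mb. The siBAZ2A list held 4257 peaks (median 549 bp, 2.46 Mb), 1.28 times the siControl number, and the siBAZ2B list held 4865 peaks (median 562 bp, 2.89 Mb), 1.46 times that number. The H3K4me3 list held 18596 peaks with a median width of 1125 bp and covered 21.5 Mb. The peaks of each list are numbered as in the replicate they were taken from, and the highest number is a lower bound of that replicate's peaks. Which of the labelled replicates it was is not known. It was 8657 in siControl, 8197 in siBAZ2A and 8847 in siBAZ2B, so the replicates with the most peaks differed far less than the lists.

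Knockdown of BAZ2A was accompanied by 1698 BG4 peaks that siControl lacked, 39.9% of the siBAZ2A list (95% interval 38.4 to 41.4). The 779 siControl peaks without a siBAZ2A peak were 23.4% of the siControl list (21.97 to 24.8). The gained peak of highest fold lay at chr7:44122019-44122540 (fold 13.3), followed by chr1:59762145-59762627 (12.7), chr16:27214783-27215422 (12.1), chrX:47092786-47093198 (11.9) and chr6:160183001-160183408 (11.6). All 10 of the strongest gained peaks overlapped H3K4me3, and all 10 were also present in siBAZ2B. The strongest lost peaks were at chr21:10819367-10819748 (fold 13.2), outside H3K4me3, and at chr9:80376715-80377163 (12.7), inside it. All 10 of the strongest lost peaks were still in the siBAZ2B list, and 9 of them overlapped H3K4me3.

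Gained peaks in siBAZ2A were mostly weak. They had a median fold of 6.26 (quartiles 5.41 and 7.27) against 7.64 (6.38 and 9.11) for the peaks shared with siControl, and a median width of 456 bp against 619 bp. The gained share fell from 63.6% of the weakest quintile of siBAZ2A peaks (60.3 to 66.8) to 14.1% of the strongest (11.9 to 16.6). Lost peaks were weak in the same way, from 49.5% of the weakest quintile of siControl peaks (45.7 to 53.3) to 4.05% of the strongest (2.80 to 5.83). With the lists set to equal length, 1109 peaks were gained and 1107 lost, numbers that this setting forces to be close.

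Knockdown of BAZ2B was accompanied by 2139 gained peaks, 44.0% of the siBAZ2B list (42.6 to 45.4), and 621 lost peaks, 18.6% of the siControl list (17.4 to 20.0). The strongest gained peaks lay at chrX:47092760-47093211 (fold 11.7), chr12:27090922-27091354 (11.1), chr12:64173617-64174019 (11.1) and chr3:99979631-99980083 (11.1). All 10 of the strongest overlapped H3K4me3, and 9 were also in siBAZ2A. The exception was the chromosome 3 locus. Among lost peaks, chr1:228361593-228362201 (fold 13.5, outside H3K4me3) and chr15:57179358-57179844 (10.6, inside H3K4me3) led, and of the 10 strongest, 8 overlapped H3K4me3 and 5 were present in siBAZ2A.

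As in siBAZ2A, the gained peaks of siBAZ2B were weaker than the shared ones, with a median fold of 5.74 against 6.64 and a median width of 465 bp against 640 bp. The gained share was 56.7% in the weakest quintile (53.6 to 59.8) and 21.0% in the strongest (18.5 to 23.6), and the lost share was 42.6% (38.9 to 46.4) and 2.85% (1.83 to 4.41). At equal list length 1263 peaks were gained and 1259 lost. The strongest peaks of both knockdowns were shared with siControl. With positions and folds of siBAZ2A, the top 5 of both held chr14:106641457-106641922 (fold 23.3), chr12:133841418-133842026 (23.03), chrY:59362907-59363509 (22.1) and chr13:110076330-110076814 (22.1). The peak at chr17:22020533-22020988 (22.5) was in the top 5 of siBAZ2A only. Only 1 of the 5 strongest shared peaks overlapped H3K4me3 in either knockdown, the locus on chromosome 12. That locus also held the H3K4me3 peak of rank 2 by fold (21.7), with nearly the same borders.

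**Figure D1:**
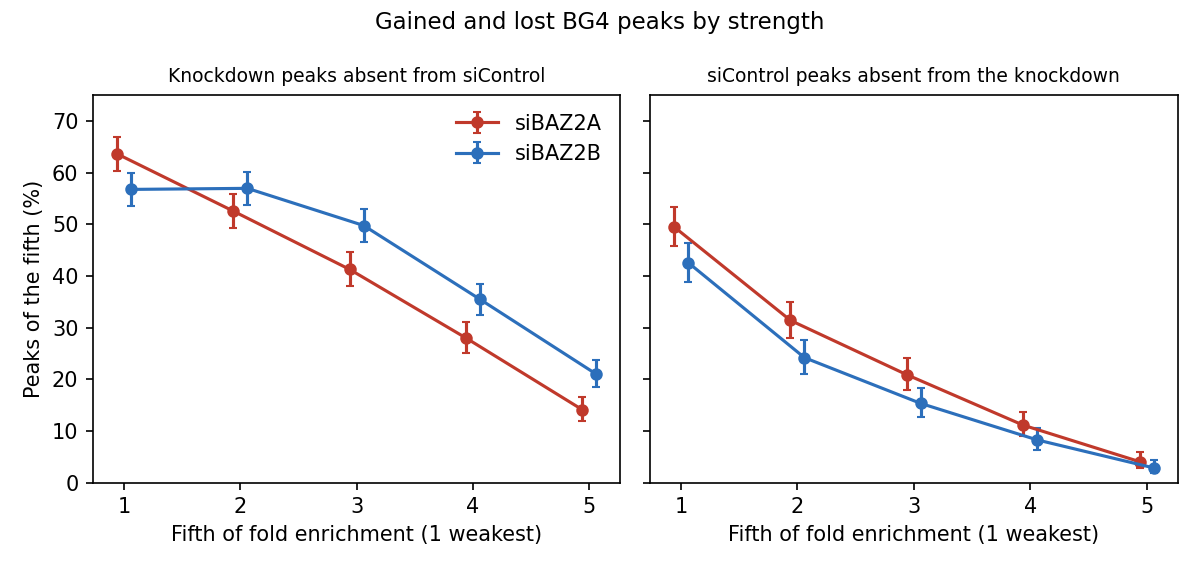
Share of BG4 peaks, in percent, that were gained (left, of the knockdown list) or lost (right, of the siControl list) in each quintile of the authors' fold enrichment, from weakest to strongest. Points are shares for siBAZ2A and siBAZ2B and bars are 95% Wilson intervals; the gained share of siBAZ2A falls from 63.6% to 14.1% and the lost share from 49.5% to 4.05%.

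The 2 knockdowns shared many of their gained loci. Merging the 3 BG4 lists gave 6206 loci, of which 2322 were in all 3 lists and 935 in both knockdowns but not in siControl. These 935 were 55.3% of the 1690 loci gained in siBAZ2A (52.9 to 57.7) and 44.0% of the 2127 gained in siBAZ2B (41.9 to 46.1). Independent lists over the 15965 BG4 or H3K4me3 loci without a siControl peak would share 225. The shared siControl list can by itself produce overlap. The quasi-symmetry model, in which every pair of lists is associated to the same degree, gave 893 loci. The observed number was 1.05 times the model value, where the model refitted to each of 500 simulated draws gave ratios of 0.971 to 1.03 in 95% of draws (simulated p of the ratio = 0.00399, not an exact test). At a −log10 q of at least 5 the ratio was 1.02 (simulated p = 0.261, not an exact test), and with lists of equal length it was 1.16, with 523 loci against 450 (simulated p = 0.002, the smallest the draws can give, not an exact test). These p-values cover counting error over loci only and do not test a difference between conditions. The model was fitted to these same counts, and in simulations it took up most of an added shared gain. Its value is therefore not the overlap that would arise without any change. The model understates a real shared gain, so the size of such a gain cannot be read from it.

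Each knockdown list had more of its peaks in the other knockdown list than in the shorter siControl list. Of the siBAZ2A peaks, 76.7% (75.5 to 77.99) had a siBAZ2B peak and 60.1% (58.6 to 61.6) a siControl peak. Of the siBAZ2B peaks, 67.4% (66.05 to 68.7) had a siBAZ2A peak and 56.03% (54.6 to 57.4) a siControl peak. Of the siControl peaks, 76.6% (75.2 to 78.0) had a siBAZ2A peak and 81.4% (80.0 to 82.6) a siBAZ2B peak. Such shares depend on list length, so they do not show which lists resemble each other most. The siBAZ2A list alone held 755 loci and the siBAZ2B list alone 1192. Loci held by siControl alone numbered 389, against 347 under the model, a difference that the model forces to equal that of the loci in both knockdowns.

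**Figure D2:**
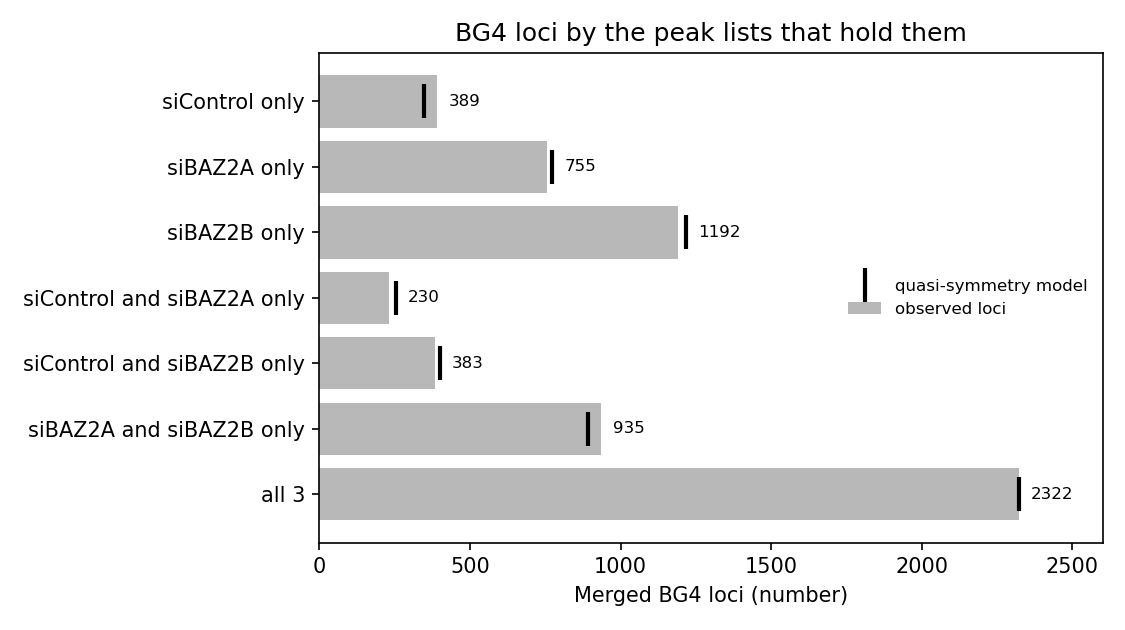
Number of merged BG4 loci (horizontal axis) for each combination of the 3 peak lists. Grey bars are observed loci and black ticks the quasi-symmetry model; loci in both knockdowns but not siControl number 935 against 893, and loci in all 3 lists number 2322.

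Most G4 peaks in every condition lay on H3K4me3-marked regions. A peak of H3K4me3 was overlapped by 89.9% of siControl BG4 peaks (88.8 to 90.9), 92.9% of siBAZ2A peaks (92.1 to 93.6) and 90.4% of siBAZ2B peaks (89.5 to 91.2). Among the BG4 peaks that overlapped H3K4me3, the median distance from the BG4 summit to the H3K4me3 summit was 122 bp in siControl, 124 bp in siBAZ2A and 128 bp in siBAZ2B. Loci held by siControl alone lay on H3K4me3 in 72.2% of cases (67.6 to 76.5), those of both knockdowns without siControl in 93.3% (91.5 to 94.7), and those of all 3 lists in 95.05% (94.1 to 95.9).

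Lost peaks lay outside H3K4me3 more often than kept peaks. In siBAZ2A, 74.8% of lost (71.7 to 77.8) and 94.5% of kept siControl peaks (93.6 to 95.3) overlapped H3K4me3 (odds ratio 0.173, Fisher's exact p = 1.47e-48, adjusted p = 5.88e-48). In siBAZ2B the shares were 79.2% (75.9 to 82.2) and 92.4% (91.3 to 93.3), with an odds ratio of 0.315 (Fisher's exact p = 2.40e-19, adjusted p = 4.81e-19). Within quintiles of fold the odds ratios were 0.267 (0.208 to 0.343) and 0.529 (0.411 to 0.682). Against the stronger 50% of H3K4me3 peaks alone they moved much closer to 1, to 0.779 for siBAZ2A (Fisher's exact p = 0.00267) and 0.820 for siBAZ2B (Fisher's exact p = 0.0284).

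The difference was smaller for gained peaks. In siBAZ2A, 90.3% of gained and 94.6% of shared peaks overlapped H3K4me3 (odds ratio 0.530, Fisher's exact p = 1.37e-07, adjusted p = 1.37e-07), and within quintiles of fold the odds ratio was 0.785 (0.612 to 1.01), no longer past the threshold. In siBAZ2B, 87.8% and 92.4% did (odds ratio 0.591, Fisher's exact p = 8.31e-08, adjusted p = 1.11e-07), with 0.682 (0.557 to 0.834) within quintiles. Against the stronger 50% of H3K4me3 peaks alone the direction turned, with odds ratios of 1.203 for siBAZ2A (Fisher's exact p = 0.00324) and 1.28 for siBAZ2B (Fisher's exact p = 2.15e-05).

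**Figure D3:**
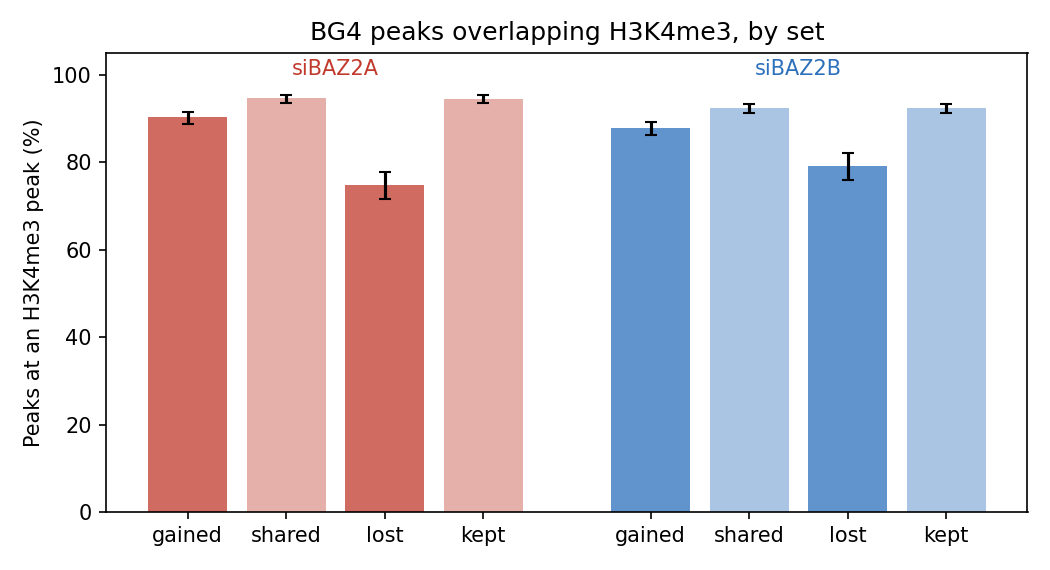
Percent of BG4 peaks overlapping an H3K4me3 peak (vertical axis), for peaks gained in or shared by each knockdown list and for siControl peaks lost or kept. Bars are shares and whiskers 95% Wilson intervals; lost peaks stand lowest, at 74.8% for siBAZ2A and 79.2% for siBAZ2B.

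Wide H3K4me3 regions carried G4 peaks most often. In siControl 16.04% of the 18596 H3K4me3 peaks (15.5 to 16.6) had a BG4 peak, in siBAZ2A 21.1% (20.5 to 21.7) and in siBAZ2B 23.4% (22.8 to 24.01). From the narrowest to the widest quintile of H3K4me3 peaks, this share rose from 5.40% (4.72 to 6.18) to 30.5% (29.1 to 32.0) in siControl, from 7.04% (6.26 to 7.91) to 38.3% (36.7 to 39.9) in siBAZ2A and from 7.82% (7.003 to 8.73) to 39.7% (38.2 to 41.3) in siBAZ2B. A wider region also has more bases in which a peak can overlap it. By fold of the H3K4me3 peak there was no such order. In siControl the share was 12.6% in the weakest quintile, 18.9% in the next and 14.1% in the strongest. The H3K4me3 peaks that gained BG4 in both knockdowns had a median width of 1389 bp, against 1447 bp for those with a siControl BG4 peak and 998 bp for those with none in any list.

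**Figure D4:**
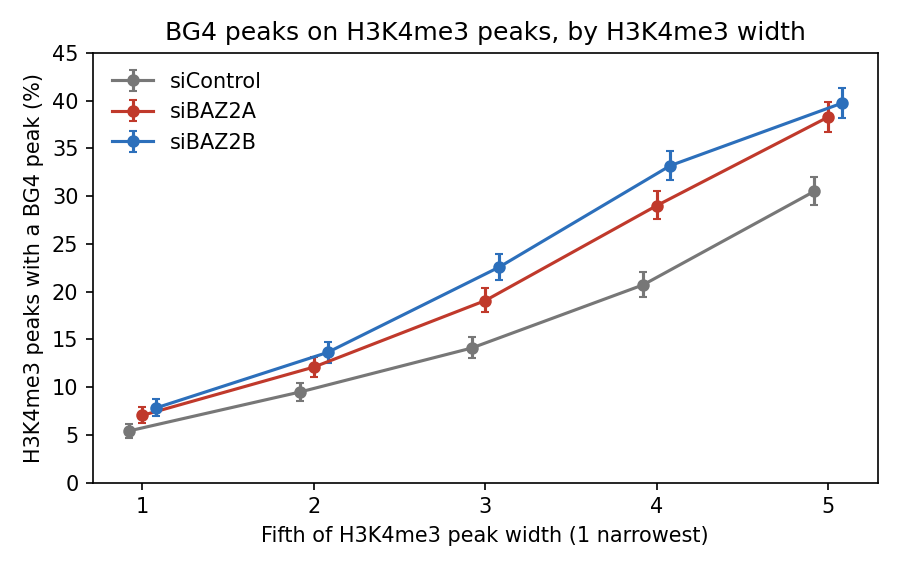
Percent of H3K4me3 peaks that carry a BG4 peak (vertical axis) in each quintile of H3K4me3 peak width, from narrowest to widest, for the siControl, siBAZ2A and siBAZ2B lists. Points are shares and bars 95% Wilson intervals; the share climbs to 30.5%, 38.3% and 39.7% in the widest quintile.

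Chromosomes 17 and 19 had the highest shares of H3K4me3 peaks with a G4 peak in siControl. They also had smaller shares of gained peaks than all other chromosomes combined. Gained peaks are by definition those absent from siControl, so these observations are not independent. The gained shares per chromosome were not stratified by fold. In siControl 25.8% of the H3K4me3 peaks of chromosome 17 (23.4 to 28.4) and 25.8% of those of chromosome 19 (23.4 to 28.3) had a BG4 peak, against 7.32% on chromosome 6 (5.79 to 9.20). Compared with all other chromosomes, the odds ratios were 1.91 (Fisher's exact p = 5.22e-19, adjusted p = 9.40e-18), 1.92 (Fisher's exact p = 1.08e-19, adjusted p = 3.90e-18) and 0.400 (Fisher's exact p = 2.10e-15, adjusted p = 3.03e-14). Chromosomes 2, 16, 17 and 19 stood above the rest at an adjusted p under 0.05 in all 3 lists, and chromosomes 4, 6, 13 and 18 below.

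In siBAZ2A, 25.9% of the BG4 peaks of chromosome 17 (Fisher's exact p = 1.43e-08, adjusted p = 2.29e-07) and 24.9% of those of chromosome 19 (Fisher's exact p = 2.49e-10, adjusted p = 5.97e-09) were gained, against 39.9% of the whole list. Chromosome 13 stood above the other chromosomes, with 61.4% (Fisher's exact p = 0.00483, adjusted p = 0.0331). In siBAZ2B, 30.7% were gained on chromosome 17 (Fisher's exact p = 3.32e-08, adjusted p = 3.99e-07) and 27.6% on chromosome 19 (Fisher's exact p = 9.74e-13, adjusted p = 4.67e-11), while chromosomes 3, 6 and 18 stood higher with 52.7%, 60.2% and 66.7% (Fisher's exact p = 0.00818, 0.000518 and 0.00436, adjusted p = 0.0491, 0.00497 and 0.0331). Peak numbers exceeded those of siControl on 22 of 24 chromosomes in siBAZ2A and on all 24 in siBAZ2B.

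G4 peaks lay near chromosome ends more often than H3K4me3 peaks. Chromosome lengths were not used here, and the far end was placed at the last peak of any list. Within 5 Mb of an end were 19.1% of siControl BG4 peaks (17.8 to 20.5), 16.5% of siBAZ2A peaks (15.5 to 17.7), 16.9% of siBAZ2B peaks (15.9 to 17.99) and 13.0% of H3K4me3 peaks (12.6 to 13.5). Gained peaks were there less often than shared ones, at 13.0% against 18.9% in siBAZ2A (odds ratio 0.644, Fisher's exact p = 5.08e-07) and 13.7% against 19.4% in siBAZ2B (odds ratio 0.658, Fisher's exact p = 1.60e-07). Within 1 Mb, a window chosen after seeing the data, the odds ratio for siBAZ2A was 0.798 (Fisher's exact p = 0.135) and that for siBAZ2B 0.701 (Fisher's exact p = 0.00877). These contrasts were not stratified by fold, although gained peaks were weaker than shared ones. Shared peaks are also by definition those at siControl peaks, and siControl was the list with the largest share near ends. Pericentromeric position was not analysed here.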

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

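The numbers that peaks carry in their names were not part of the planned comparisons, and the tests on them, as well as the reading of the H3K4me3 odds ratios as tests of an explanation, were chosen after the results were seen. The numbers show how much of the largest replicate stayed in each list. In siBAZ2A 51.9% of the numbered peaks stayed (50.9 to 53.01) and in siBAZ2B 55.0% (54.0 to 56.0), both above the 38.5% of siControl (37.5 to 39.5). Matching peaks between lists by these numbers assumes that the peak caller numbered peaks in order of position along each chromosome.

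The first pattern is that both knockdown lists are longer than the siControl list. More peaks in the largest replicate cannot account for it, since the highest peak numbers stood at 0.947 (siBAZ2A) and 1.02 (siBAZ2B) of the siControl number while the lists stood at 1.28 and 1.46. Gained peaks may be sites called in only 1 siControl replicate, and of those at H3K4me3 that lay between 2 siControl peaks of their chromosome (1517 and 1858), 94.3% (siBAZ2A) and 93.8% (siBAZ2B) could be matched with a siControl peak dropped between the same neighbours, against 88.8% and 87.7% for random H3K4me3 peaks, with none of 1000 draws as high. Lost siControl peaks placed in the same way matched dropped knockdown peaks beyond random as well, with 88.2% against 79.3% in siBAZ2A (0 of 1000 draws as high) and 83.3% against 79.3% in siBAZ2B (13 draws), so the match is not particular to the longer lists and leaves this explanation open. Unequal depth of the replicates cannot be told apart from a change in G4 structures after knockdown, because the files hold neither depths nor replicates behind the 51.9% and 55.0%.

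The other pattern is that siControl peaks lost in a knockdown lie on H3K4me3 less often than kept ones. Low fold of the lost peaks did not account for all of it. Within quintiles of fold the odds ratios remained 0.267 in siBAZ2A and 0.529 in siBAZ2B, with intervals below 1. Quintiles are coarse, and peak width was not adjusted for (median 426 bp in siBAZ2A lost peaks, 643 bp in kept ones). The share due to weakness therefore cannot be bounded. The pattern was much smaller against the stronger 50% of H3K4me3 peaks alone, with odds ratios of 0.779 and 0.820. Peaks on chromosome M, chromosome Y and contigs are not its cause, with odds ratios of 0.181 and 0.302 without them. Whether sites at weak or no H3K4me3 are lost after depletion of BAZ2A or BAZ2B, or are less repeatable in any condition, stays open as a hypothesis that was not tested.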

How the results depend on the processing

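No paired analysis was possible because each list merges its 4 replicates, and for the same reason no replicate could be left out. Of 67 alternative values, 53 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times the main count, 3 lost the threshold, 9 counts moved and 2 values turned direction. With lists of equal length the gained peaks numbered 1109 (siBAZ2A) and 1263 (siBAZ2B), the loci gained in both 523 (1.16 times the model) and the peaks lost in siBAZ2B 1259, which follows from the shorter lists. With the stronger 50% of a list, 521 and 788 peaks were gained, 155 and 119 lost, and 219 loci gained in both, since weak peaks are left out. At a −log10 q of at least 5 the ratio of loci gained in both to the model was 1.02. Against the stronger 50% of H3K4me3 peaks the odds ratio of gained against shared peaks turned to 1.203 (siBAZ2A) and 1.28 (siBAZ2B), that of lost against kept peaks moved to 0.779 and 0.820, and within quintiles of fold that of gained peaks was 0.785 in siBAZ2A. The odds ratio for siBAZ2A gains within 1 Mb of chromosome ends was 0.798 (0.701 for siBAZ2B), an alternative chosen after seeing the data, as was equal list length for chromosome ends. The cause was not tested for these last changes. Counting peaks as deposited changed nothing, because no peaks overlap within a list. The distance of up to 1 kb acted on merged loci only, with 931 loci gained in both. Its gained and lost peak counts repeat the main ones, so this distance was not tested for them, though they are among the 53. Alternatives for promoters, G4 motifs and gene lists were not run. Read depth, which sets how many weak peaks are called, is unknown, and the intervals and p-values cover counting error only.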

Other observations

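The contig gl000220, which carries copies of the ribosomal RNA gene repeat silenced by BAZ2A, held 5 BG4 peaks in siControl, 4 in siBAZ2A and 7 in siBAZ2B. Which of these peaks lie within the repeat copies was not analysed here. The strongest of the siControl peaks, at 6998-8251, had a fold of 11.05 against the list's median of 7.05. Both knockdown lists also had their strongest peak of the contig there, and H3K4me3 had a peak there too, at 6716-8296 (fold 7.47). The siControl peaks at 105182-106961 (fold 2.79) and 149154-150911 (2.90) were low in fold for their list. Their −log10 q of 8.33 and 9.28 lay near the list's median of 8.93. At the same regions siBAZ2A had 1 peak each, 104738-106797 and 148708-150864, and siBAZ2B had 3 and 2 shorter peaks. The mitochondrial genome held 2 BG4 peaks in siControl, with folds of 1.88 and 2.01, and 3 peaks in each knockdown. The H3K4me3 list also held 3 peaks there, with folds of 2.16 to 2.70, so peaks on this genome were not particular to BG4. These loci were chosen after their values were seen.

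Many BG4 peaks at the tips of chromosomes were strong. The far tip was again placed at the last peak of any list. It holds a peak by construction, so the counts cannot show that peaks are enriched there. Within 20 kb of a chromosome end lay 22 siControl, 19 siBAZ2A and 25 siBAZ2B peaks, and 9, 7 and 11 of these were among the 50 strongest peaks of their list. Of the 50 strongest siControl peaks, 49 were in all 3 BG4 lists, as were 49 in siBAZ2A and 48 in siBAZ2B. H3K4me3 was overlapped by 78% of the 50 strongest siControl peaks (64.8 to 87.2) against 90.1% of the others (Fisher's exact p = 0.0141, adjusted over 3 tests 0.0212). In siBAZ2B the shares were 62% (48.2 to 74.1) and 90.7% (Fisher's exact p = 6.00e-08, adjusted p = 1.80e-07), and in siBAZ2A 88% (76.2 to 94.4) and 92.9% (Fisher's exact p = 0.166, adjusted p = 0.166). Only 2 gained siBAZ2A peaks and 4 gained siBAZ2B peaks lay within 20 kb of an end. The tip window and the number of strongest peaks were chosen after seeing the data.

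The H3K4me3 list led with chr3:73159814-73160319 (fold 23.4), chr12:133841412-133842014 (21.7), chrX:155259889-155260496 (20.9), chr1:247289628-247290334 (18.8) and chr1:142890453-142891147 (18.8). The first 3 of these 5 had a BG4 peak in every list, the fifth had one in both knockdowns only, and the locus at chr1:247289628-247290334 had none.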
